A study of Rattus norvegicus with 23 samples.

How the data were processed

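Small RNA was sequenced from cauda epididymal sperm of 23 male Long-Evans rats: 7 exposed to filtered air, 8 to 0.4 ppm ozone and 8 to 0.8 ppm ozone. The design text names 8 rats per group, and the labels list 7 air libraries. Per the labels' protocols, exposures lasted 4 h, with 3 in the first week and 2 in the second, and the chambers averaged 0.401 and 0.798 ppm. RNA shorter than the kit's size limit was isolated with the mirVana procedure, libraries were made with the CleanTag small RNA kit, and single-end reads of 75 cycles were taken on a NextSeq 500. The labels give RNA integrity numbers of 2 to 4 over all samples and none per sample.

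The submitters' processing notes name Partek, Bowtie 1.0.0 and the build rn6. How reads were assigned to each kind of RNA, and how length was filtered, is not given in the sources used here. The deposited values are a scaled read signal in 4 tables: 425 miRNA rows, 273 tRNA rows, 30676 piRNA rows and 617 rows of Ensembl transcripts. Every deposited column was matched to a labelled rat. In each table the median ratio of a library to the geometric mean of all libraries was equal in the 23 libraries, so each table had been scaled on its own rows by a median-ratio factor. Levels were therefore compared within a table and never between tables. Of the miRNA values checked, 100% were whole multiples of 1 step within 0.1 of a read, with 292 to 355 values checked in each library. This recovered whole reads, from 213839 to 1286612 per library. In the tRNA table the same step gave 164342 to 481504 reads per library, but few values were low enough to test the step firmly, and no count test was run on it. The piRNA and Ensembl values are fractional, their depth is unknown, and 15512 piRNA rows repeated an earlier row exactly, leaving 15164 distinct rows. Such rows share reads, as do near-identical tRNA genes, so a count of tRNA rows can hold the same signal more than once. The design text speaks of noncoding RNA, and the Ensembl table holds 496 transcripts whose names match nuclear protein-coding genes of the GRCr8 RefSeq annotation, 15 mitochondrial noncoding transcripts, 7 mitochondrial mRNAs, 1 pseudogene and 98 with no RefSeq match. That annotation is of another build than the reads and was used for names and classes only.

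The comparisons, lists, naming rule and main tests were chosen before the data were examined, except the adjustment of the library measures described below. Features above 0 in at least 8 of the 23 libraries were tested, which kept 407 miRNAs and every row of the other tables. limma 3.58.1 in R 4.3.3 was fitted to log2(value + 1) with a mean-variance trend and robust moderation, over all 3 groups in 1 model. The contrasts were 0.4 ppm against air, 0.8 ppm against air, 0.8 ppm against 0.4 ppm, and a linear trend with ppm. Adjusted p is Benjamini-Hochberg within a table and contrast, two-sided, at 0.05. Log2 fold changes are on the log2(value + 1) scale, which understates the change of low features. Intervals are 95% intervals from the same model.

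Lists of miRNAs and of mRNAs were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a table within each contrast. The miRNA lists were the miR-34/miR-449, X-linked miR-506, let-7, miR-10/miR-99/miR-100/miR-125, miR-200 and miR-17-92 families, erythroid, leukocyte, and muscle and stroma markers, miRNAs tied to paternal stress in mice, and redox and hypoxia responsive miRNAs. The mRNA lists for sperm, epididymal epithelium, leukocytes and erythrocytes had 1 measured gene between them, Lcn5, and could not be tested. tRNA rows were listed by isotype and anticodon where at least 3 rows were present, and Ensembl rows by class. Shares of a table held by a family, and measures of each library, were compared between groups by two-sided exact permutation of the difference of means over every relabelling, with Benjamini-Hochberg adjustment over the 15 families or the 9 library measures within a contrast. The set over which the library measures were adjusted was chosen after the data were seen, so the values over wider sets are given too. Correlations across libraries have permutation p-values from 100000 random orders.

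Features were named by a fixed rule: the 10 largest changes past 0.05; where fewer than 5 passed, the 3 smallest unadjusted p-values, given as values that did not pass; the 5 most abundant features of each table; up to 4 abundant members of each list; and up to 5 features called under an alternative alone. An Ensembl transcript that the rule names at 0.8 ppm is not reported here. The alternatives were other pseudocounts, filters and scalings, quantile normalization, library weights, an exact Wilcoxon rank-sum test for each pair of groups, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered miRNA reads, fits to the compared groups alone, a residual principal component as covariate, summed tRNA rows, and leaving out each rat. Alternatives chosen after seeing the data were piRNA rows of identical values kept once, and depth as a covariate. Depth as a covariate was log2 miRNA reads in every table, so tRNA, piRNA and Ensembl fits were not adjusted for their own depth. Also chosen then were leaving out the 3 libraries with fewest miRNA reads, and leaving out each rat for the library measures and list tests.

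The fit was tested on simulated data for 0.8 ppm against air, made from the real residuals with library order shuffled and known folds added. Over 20 runs it recovered 94% of miRNAs, 100% of tRNA rows, 46.1% of piRNA rows and 90% of Ensembl transcripts changed 4-fold. At 2-fold it recovered 51.5%, 86.3%, 5.3% and 34.8%, and at 1.5-fold 19.3%, 34.5%, 1.12% and 5.75%. Those runs used 407, 273, 30676 and 617 features, of which 60, 60, 200 and 60 were changed in each run. With fewer changed features the adjusted threshold is stricter, so these rates do not give the recovery of a few changed features, which may be lower. Over all runs 8.22% of the calls were false for miRNAs, 4.85% for tRNA rows, 67.2% for piRNA rows and 4.04% for Ensembl transcripts, where 5% is the intended rate. The median per run was 3.03%, 2.04%, 0% and 0%, so a few runs held most false piRNA calls. Intervals on read shares cover counting error only, since PCR copies are not independent molecules.

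The index numbers in the sample titles run from 1 to 12, and 11 of them occur on 2 libraries, so the libraries may have been run in more than 1 pool. The labels do not say which library was in which pool, and no batch term could be fitted.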

Results

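Small RNA of mature sperm from the cauda epididymis, the duct's storage segment, was profiled in rats that had breathed filtered air (n = 7), 0.4 ppm ozone (n = 8) or 0.8 ppm ozone (n = 8) in 5 exposures over 2 weeks. The study asked whether ozone, an oxidant air pollutant, alters the noncoding RNA that sperm carry. Recovered miRNA reads ranged from 213839 to 1286612 per library with a median of 628270, and tRNA reads from 164342 to 481504 with a median of 391901. Mean miRNA reads were 727310 ± 273960 in air (SD, n = 7), 582920 ± 334630 at 0.4 ppm (n = 8) and 747880 ± 334310 at 0.8 ppm (n = 8), and neither ozone group was separated from air (exact permutation p = 0.379 and 0.899). No pair of libraries held identical values. The rats are separate animals, so p-values of single features, of fry and of the permutation tests measure the spread between animals. Camera p-values at the preset correlation rest on an assumed correlation of 0.01 between list members, so they can overstate a list change.

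The sperm miRNA pool was dominated by the miR-34/miR-449 family, which is abundant in meiotic and post-meiotic germ cells. miR-34c-5p alone held 24.6% ± 5.14 of the miRNA table (SD, n = 23), from 13.3% to 32.4% in single libraries. In the shallowest library it held 21.9%, with a 95% Wilson interval of 21.7% to 22.0%. miR-34b-3p followed with 6.91% ± 1.23, miR-449a-5p with 5.95% ± 1.15, miR-30a-5p with 3.96% ± 0.921 and miR-10a-5p with 3.88% ± 2.34 (each SD, n = 23). Among the germ-cell miRNAs of the X-linked miR-506 cluster, miR-743b-3p averaged 4462 ± 472 in normalised value in air (SD, n = 7) and miR-743a-3p 3569 ± 584. Members of the lists for other cells were also present, and whether they came from such cells was not tested. In air, the leukocyte list was led by miR-146b-5p at 17071 ± 6368, the muscle and stroma list by miR-143-3p at 12214 ± 3618, the epithelial miR-200 list by miR-141-3p at 3160 ± 1384, and the erythroid list by miR-451-5p at 166.6 ± 59.2 (SD, n = 7). As shares of the table these lists held 2.88% ± 0.9, 1.95% ± 0.523, 1.14% ± 0.325 and 0.0528% ± 0.0205 in air. The leukocyte and the muscle and stroma shares are mostly 1 miRNA each, since miR-142-5p averaged 331.6 ± 68.4, miR-150-5p 46.0 ± 10.8, miR-145-5p 33.5 ± 9.18 and miR-1-3p 16.4 ± 6.92 in air (SD, n = 7).

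Reads assigned to tRNA-Gly-GCC held 32.6% ± 3.63 of the tRNA table in air (SD, n = 7), tRNA-Leu-CAA 18.4% ± 3.72, tRNA-Gly-CCC 8.63% ± 0.946 and tRNA-Glu-CTC 6.54% ± 0.764. The single rows with the most signal were tRNA-Leu-CAA-2-2 at 9.14% ± 2.11 of the table and tRNA-Gly-GCC-1-5 at 8.12% ± 1.3 (SD, n = 23), and the Gly-GCC rows are near-identical genes whose reads cannot be assigned to 1 copy. The Gly-CCC share may hold the same reads, since tRNA-Gly-CCC-1-1 held 7.94% ± 1.33 and its log2 value followed that of tRNA-Gly-GCC-1-5 over libraries (Pearson r = 0.9995). The most abundant piRNA, piR-rno-3104129, held 3.2% ± 1.01 of its table. In the Ensembl table reads assigned to the mitochondrial transcript AY172581.24 held 41.3% ± 11.0, to a transcript of Stat2, an interferon signalling factor, 10.9% ± 8.65, to one of the olfactory receptor gene Olr1568 6.42% ± 5.14 and to one of the protocadherin gene Pcdhga7 5.31% ± 3.06 (SD, n = 23). In single libraries Stat2 reached 37.8% and Olr1568 27.2%. These are small RNA reads whose position in the transcript is not given, and whether they come from mRNA of these genes was not tested. Lcn5, an epididymal lipocalin, averaged 86.4 ± 25.2 in air (SD, n = 7), 83.5 ± 31.2 at 0.4 ppm and 83.2 ± 37.1 at 0.8 ppm (n = 8 each).

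At 0.4 ppm, no miRNA passed the adjusted threshold against air. The smallest unadjusted p-values belonged to miR-429, a miR-200 family member, with a log2 fold change of 0.72 ± 0.25 (SE) and a 95% interval of 0.22 to 1.22, to miR-3590-5p with -0.84 ± 0.29, and to miR-136-3p with -1.12 ± 0.41; the limma adjusted p was 0.784 for each. The 8 measured members of the miR-200 family, which marks epithelium such as the epididymal lining, had positive fold changes with a median of 0.53, and miR-141-3p averaged 4870 ± 1880 (SD, n = 8) against 3160 ± 1384 in air. None passed over all miRNAs, and 2 passed when adjusted over the list alone, miR-429 and miR-141-3p (limma adjusted p = 0.0433 for both). With the preset correlation camera called the miR-200 family higher (adjusted p = 8.91e-05), which did not hold with an estimated correlation (adjusted p = 0.134). fry, a test that allows for correlation between members, called no list in any table or contrast; its smallest adjusted p was 0.167, for the miR-200 and the muscle and stroma miRNA lists at 0.4 ppm. The miR-10/miR-99/miR-100/miR-125 family (7 of 7 members positive, median 0.39, adjusted p = 7.23e-04) and the muscle and stroma list (5 of 5 positive, median 0.36, adjusted p = 0.0239) were called higher in the same way. With an estimated correlation their adjusted p-values were 0.293 and 0.134. The miR-34/miR-449 family (0 of 6 positive, median -0.39, adjusted p = 0.0074) and the miR-17-92 and related clusters (0 of 9 positive, median -0.27, adjusted p = 0.0239) were called lower, and with an estimated correlation their adjusted p-values were 0.365 and 0.418. No member of these 4 lists passed adjusted over the list alone. With miRNA read depth as a covariate the miR-34/miR-449 family, the miR-17-92 clusters, and the muscle and stroma list were no longer called (adjusted p = 0.0806, 0.652 and 0.0592). Quantile normalization ended the miR-34/miR-449 call (adjusted p = 0.135), and per-million and quantile scaling left the sign of the median of each of the 5 called miRNA lists as it was. With each rat left out in turn, the miR-200, miR-10 and miR-34/miR-449 calls stayed in all 23 fits, and those of the muscle and stroma list and the miR-17-92 clusters in 18. Their medians over these fits ran from 0.40 to 0.63 for miR-200, 0.32 to 0.50 for miR-10, -0.46 to -0.26 for miR-34/miR-449, 0.24 to 0.44 for muscle and stroma, and -0.42 to -0.15 for miR-17-92.

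Families and lists taken as shares of the table gave differences that did not pass adjustment over the 15 families. The muscle and stroma share sums 6 miRNAs, of which 5 were tested as a list. The miR-34/miR-449 family held 35.6% ± 6.50 at 0.4 ppm (SD, n = 8) against 42.6% ± 5.46 in air (n = 7; exact permutation p = 0.0441, adjusted p = 0.14). The let-7 family, which is widespread in differentiated cells, held 10.1% ± 1.79 against 8.01% ± 1.82 (exact permutation p = 0.0483). The miR-200 list held 1.78% ± 0.716 against 1.14% ± 0.325 (exact permutation p = 0.0325), and the muscle and stroma list 2.85% ± 0.704 against 1.95% ± 0.523 (exact permutation p = 0.0152), each with an adjusted p of 0.14. Without air replicate 6 the miR-34/miR-449, let-7, and muscle and stroma differences passed (adjusted p = 0.0433), with differences of -8.94, 2.66 and 1.04 percentage points. Without air replicate 1 the tRX-Gly-NNN share of the tRNA table passed, with a difference of 1.18 percentage points (adjusted p = 0.04995 by the exact permutation test), against 0.878 with every rat (adjusted p = 0.14). The leukocyte share was 3.3% ± 1.57 at 0.4 ppm against 2.88% ± 0.9 (exact permutation p = 0.582) and the erythroid share 0.0839% ± 0.0687 against 0.0528% ± 0.0205 (exact permutation p = 0.279).

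The other fixed miRNA lists were not called at 0.4 ppm with the preset correlation. let-7 had a median log2 fold change of 0.23 (adjusted p = 0.0568, and called in 6 of 23 fits with 1 rat left out), the X-linked miR-506 cluster 0.03 (adjusted p = 0.862), and the erythroid list 0.05, the miRNAs tied to paternal stress -0.07, and the redox and hypoxia list -0.01. The leukocyte list had a negative median of -0.03 and a positive mean of 0.04, and its test pointed up; the redox and hypoxia list had a positive mean of 0.01, and its test pointed down. The 10 most abundant miRNAs of each library held 59.7% ± 1.98 of the table at 0.4 ppm (SD, n = 8) against 62.7% ± 1.89 in air (n = 7; exact permutation p = 0.0126), which did not pass adjustment over 9 measures (adjusted p = 0.113). Without air replicate 6 that difference passed at -3.49 percentage points (adjusted p = 0.048).

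**Figure D1:**
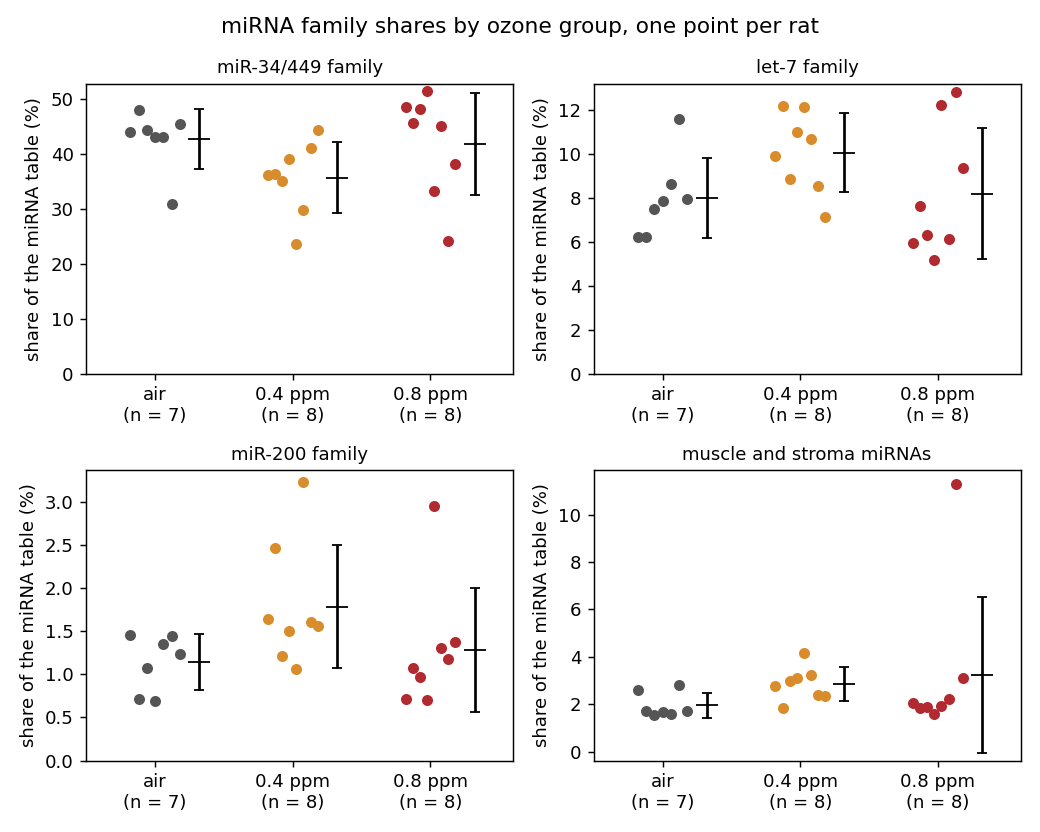
Share of the miRNA table (%, vertical axis) held by 4 fixed lists in each rat, by group; points are rats, and the bars beside them are the mean and SD, which reaches just below 0 in 1 panel. The mean miR-34/miR-449 share was 42.6% in air, 35.6% at 0.4 ppm and 41.7% at 0.8 ppm, and 1 rat at 0.8 ppm stands at 11.3% in the muscle and stroma panel.

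tRNA, piRNA and Ensembl rows also gave 0 calls at 0.4 ppm. The smallest unadjusted p-values among tRNA rows were those of tRX-Val-NNN-3-1, tRNA-Trp-CCA-1-1 and tRNA-Ser-AGA-4-1 (limma adjusted p = 0.627). Their log2 fold changes were 0.97 ± 0.34 (SE), 0.85 ± 0.31 and -0.62 ± 0.23. The row tRX-Val-NNN-3-1 was low, at 8.40 ± 3.95 (SD, n = 8) against 3.93 ± 2.67 in air (n = 7). So was tRNA-Trp-CCA-1-1, at 11.5 ± 6.99 against 5.54 ± 2.03. If the step found in the tRNA table holds, 1 read was worth 0.708 to 1.38 in air libraries. The 7 rows of tRNA-Ser-AGA were all negative, with a median of -0.55, and were called lower with the preset correlation (adjusted p = 6.41e-05), but the adjusted p was 0.547 with an estimated correlation. Adjusted over the list alone, 4 of the 7 rows passed (smallest limma adjusted p = 0.0375). These 7 rows may share reads, so they may not be separate signals. Over their own lists, 1 of 3 tRX-Val-NNN rows (limma adjusted p = 0.0206) and 1 of 4 tRNA-Ser-TGA rows (0.0488) passed. None of these rows passed over all tRNA rows. The Ser-AGA call stayed with each rat left out, with medians from -0.67 to -0.34. The other 9 called tRNA lists had an adjusted p of 0.547 or more with an estimated correlation. They stayed called in 9 to 20 of the 23 fits with 1 rat left out. Several of their calls also ended with miRNA read depth as a covariate or with quantile normalization. Among piRNAs, piR-rno-227431 stood at 0.358 ± 0.197 (SD, n = 8) against 5.71 ± 3.95 in air (n = 7). Its log2 fold change was -2.03 ± 0.35 (SE, limma adjusted p = 0.134). Those of piR-rno-1361373 and piR-rno-346434 were -2.68 ± 0.56 and 2.41 ± 0.52 (SE, limma adjusted p = 0.653 for both). Their values were 2.42 ± 4.34 against 13.9 ± 4.54 in air, and 11.6 ± 7.41 against 0.835 ± 0.692 (SD). Such values are low in a table whose most abundant row averaged 429630. Without air replicate 2, piR-rno-227431 passed the threshold with a log2 fold change of -2.36, and without 0.4 ppm replicate 5, piR-rno-346434 passed with 2.87. In the Ensembl table the smallest unadjusted p-values were those of transcripts of Srsf4, a splicing factor, with -0.85 ± 0.31, Pcdh7, a protocadherin, with -1.07 ± 0.39, and Synpo2, an actin-binding protein, with -1.49 ± 0.55 (limma adjusted p = 0.971). At an unadjusted p under 0.05 limma gave 22 of 407 miRNAs, 16 of 273 tRNA rows, 1417 of 30676 piRNA rows and 19 of 617 Ensembl transcripts, where chance gives 20.4, 13.7, 1534 and 30.9. edgeR and DESeq2 on the recovered miRNA reads also gave 0 calls, with 26 and 31 miRNAs at an unadjusted p under 0.05. With library weights limma called 2 miRNAs at 0.4 ppm, miR-3590-5p and miR-429 (adjusted p = 0.0468 for both).

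At 0.8 ppm, no feature of any table passed the adjusted limma threshold against air. The miRNAs with the smallest unadjusted p-values were miR-17-2-3p with a log2 fold change of 0.90 ± 0.31 (SE), miR-3588 with 0.61 ± 0.25 and miR-125b-5p with 0.59 ± 0.26 (limma adjusted p = 0.993). Of the 16 measured miRNAs of the X-linked miR-506 cluster, which testis germ cells express, 15 had positive fold changes with a median of 0.30, and none passed adjusted over the list alone or over all miRNAs. The cluster was called higher with the preset correlation (adjusted p = 0.0023), as were the miR-200 family (7 of 8 positive, median 0.17, adjusted p = 0.0368) and the muscle and stroma list (5 of 5 positive, median 0.37, adjusted p = 0.0481). With an estimated correlation their adjusted p-values were 0.186, 0.577 and 0.186. The calls of the miR-200 and of the muscle and stroma miRNA list also ended with depth as a covariate (adjusted p = 0.0852 for both), with quantile normalization (0.0544 and 0.0737) and with a residual component as covariate (0.0506 for both). With each rat left out in turn, the X-linked call stayed in all 23 fits, the miR-200 call in 17, and the muscle and stroma call in 11. Without 0.8 ppm replicate 5 the miR-200 median was 0.07 (adjusted p = 0.475), and without 0.8 ppm replicate 7 the muscle and stroma median was 0.18 (adjusted p = 0.28). The medians ran from 0.21 to 0.35 for the X-linked cluster, 0.07 to 0.25 for miR-200 and 0.18 to 0.48 for muscle and stroma. The miR-34/miR-449 family held 41.7% ± 9.25 of the table (SD, n = 8) against 42.6% ± 5.46 in air (n = 7; exact permutation p = 0.836), and none of the 15 family shares passed. The miR-34/miR-449 list had a median log2 fold change of 0.01, miR-17-92 0.10, let-7 -0.10, miR-10/miR-99/miR-100/miR-125 0.23 (adjusted p = 0.0791, and called in 6 of 23 fits with 1 rat left out), the paternal-stress list -0.04, and the redox and hypoxia list 0.04, and none of these was called at 0.8 ppm with every rat kept. Without 0.8 ppm replicate 7 let-7 was called lower (median -0.27, adjusted p = 0.0196). The leukocyte and erythroid lists had positive medians of 0.07 and 0.01, means of 0.04 and -0.06, and tests that pointed down, and neither was called.

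At 0.8 ppm the most abundant tRNA rows held less of the tRNA table. The 10 most abundant rows of each library held 59.6% ± 2.67 of the tRNA table (SD, n = 8) against 64.1% ± 1.12 in air (n = 7), a difference of -4.48 percentage points (exact permutation p = 0.0014, adjusted p = 0.0126 over 9 measures). The adjusted p was 0.0154 over 11 measures with read totals added, and 0.0378 over the 27 tests of all 3 contrasts. Of the 8 libraries at 0.8 ppm, 6 lay below the lowest air library at 62.4%. The 0.4 ppm group held 62.9% ± 3.94 (n = 8) and did not differ from air by more than the spread (exact permutation p = 0.453). The 50 most abundant rows did not separate the groups, with a difference of -1.6 percentage points (adjusted p = 0.415 by the exact permutation test). Among the abundant rows, tRNA-Gly-GCC-1-5 stood at 23988 ± 10401 (SD, n = 8) against 31823 ± 6653 (n = 7), and tRNA-Leu-CAA-2-2 at 27799 ± 5622 against 37823 ± 8203, neither past the limma threshold.

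**Figure D2:**
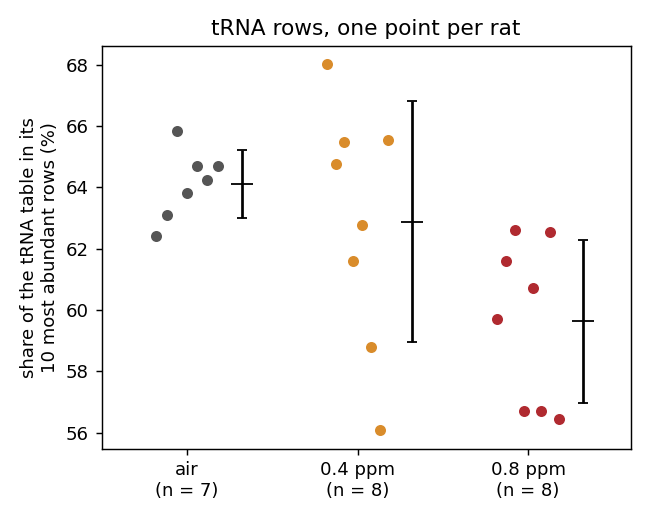
Share of the tRNA table held by the 10 most abundant rows of each library (%, vertical axis, not starting at 0), by group; points are rats, and the bars beside them are the mean and SD. The 0.8 ppm libraries lie between 56.4% and 62.6%, and the air libraries between 62.4% and 65.8%.

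Single tRNA rows with the smallest unadjusted p-values at 0.8 ppm were tRNA-Gln-CTG-2-2 (limma adjusted p = 0.293), tRX-Val-NNN-3-1 and tRNA-Ser-AGA-2-1. Their log2 fold changes were 0.96 ± 0.27 (SE), 0.85 ± 0.34 and -0.55 ± 0.23. The row tRNA-Gln-CTG-2-2 was low, at 20.8 ± 5.18 (SD, n = 8) against 10.9 ± 4.95 in air (n = 7). So was tRX-Val-NNN-3-1, at 7.63 ± 3.51 against 3.93 ± 2.67. By isotype, tRNA-Gln-CTG (8 of 9 rows positive, median 0.35, adjusted p = 2.58e-04) was called higher with the preset correlation, and tRNA-Gly-GCC (0 of 11 positive, median -0.29), tRNA-Ser-AGA (0 of 7 positive, median -0.43) and tRNA-Leu-CAA (0 of 3 positive, median -0.43) lower. With an estimated correlation their adjusted p-values were 0.586, 0.903, 0.586 and 0.591. Adjusted over the list alone, 1 of 9 tRNA-Gln-CTG rows (limma adjusted p = 0.00966) and 1 of 3 tRX-Val-NNN rows (0.0498) passed, none in the other lists and none over all tRNA rows. Quantile normalization ended the Gly-GCC and Leu-CAA calls (adjusted p = 0.309 for both). Per-million scaling moved the median of all tRNA rows from -0.02 to 0.28, and under it the Gly-GCC median turned from -0.29 to 0.01, below that of all rows. The Ser-AGA, Leu-CAA and Gln-CTG medians kept their sign at -0.13, -0.12 and 0.66. tRNA-Asp-GTC (14 of 14 positive, median 0.11) and tRNA-His-GTG (10 of 10 positive, median 0.16) were also called higher with the preset correlation, and their adjusted p was 0.907 with an estimated correlation. Taking miRNA read depth as a covariate ended the Asp-GTC call (adjusted p = 0.0511), and quantile normalization ended the His-GTG call (adjusted p = 0.496). With each rat left out in turn, the Gln-CTG, Gly-GCC and Ser-AGA calls stayed in all 23 fits, the Leu-CAA call in 21, the Asp-GTC call in 16 and the His-GTG call in 12. Without 0.8 ppm replicate 5 the Asp-GTC median was -0.03 (adjusted p = 0.68) and the His-GTG median 0.04 (adjusted p = 0.45). Among piRNAs, piR-rno-3926760 had a log2 fold change of 2.44 ± 0.53 (SE), piR-rno-227431 of -1.41 ± 0.35 and piR-rno-807920 of 2.10 ± 0.53. None passed (limma adjusted p = 0.9995 for each). All were low. In value, piR-rno-3926760 stood at 16.5 ± 8.00 (SD, n = 8) against 3.86 ± 5.81 in air (n = 7). The others stood at 1.22 ± 0.938 against 5.71 ± 3.95, and 19.2 ± 11.3 against 3.11 ± 0.991. In the Ensembl table Ccr1l1, a chemokine receptor gene, had -0.98 ± 0.30 and Tgfbr1, a TGF-beta receptor, 0.82 ± 0.29 (smallest limma adjusted p = 0.997). No class of Ensembl transcript was called: the 15 mitochondrial noncoding transcripts had a median of 0.16 (adjusted p = 0.434) the 7 mitochondrial mRNAs -0.12 (adjusted p = 0.902) and the 496 nuclear protein-coding ones -0.03 (adjusted p = 0.902). Under per-million scaling, which moved the median of all Ensembl transcripts from -0.03 to -0.21, the mitochondrial noncoding median was -0.02. Without 0.8 ppm replicate 5 these transcripts were called higher with the preset correlation (median 0.33, adjusted p = 0.0212). Fits with a rat left out were judged with that correlation alone. At 0.4 ppm these 3 classes had medians of -0.01, 0.04 and -0.01 (adjusted p = 0.955). At an unadjusted p under 0.05 limma gave 9 miRNAs, 5 tRNA rows, 723 piRNA rows and 12 Ensembl transcripts. edgeR and DESeq2 gave 0 calls, with 15 and 18 miRNAs at an unadjusted p under 0.05. With library weights limma called 3 miRNAs (miR-471-5p, miR-17-2-3p and miR-741-3p) and 22 tRNA rows at 0.8 ppm.

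Between the ozone groups, and for a linear trend with ppm, limma called 0 features in every table. Against 0.4 ppm, the 0.8 ppm group had 15 miRNAs, 6 tRNA rows, 804 piRNA rows and 14 Ensembl transcripts at an unadjusted p under 0.05, and the trend had 9, 5, 715 and 12. edgeR and DESeq2 also gave 0 calls, with 18 and 25 miRNAs at an unadjusted p under 0.05 between the ozone groups and 15 and 20 for the trend. With the preset correlation the miR-34/miR-449 family (6 of 6 positive, median 0.37), the miR-17-92 clusters (8 of 9 positive, median 0.30) and the X-linked cluster (13 of 16 positive, median 0.21) were called higher at 0.8 than at 0.4 ppm, and let-7 (1 of 9 positive, median -0.28) and miR-200 (2 of 8 positive, median -0.19) lower. Their adjusted p-values were 0.00792, 0.00823, 0.0279, 0.00823 and 0.0368 with the preset correlation and 0.36 or more with an estimated correlation. Quantile normalization ended the miR-34/miR-449 and miR-200 calls (adjusted p = 0.0758 for both), depth as a covariate those of let-7 and miR-200 (0.0594 and 0.188), and a residual component as covariate that of miR-200 (0.0564). With each rat left out in turn, the miR-34/miR-449, miR-17-92 and let-7 calls stayed in all 23 fits, the X-linked call in 18 and the miR-200 call in 16, and the miR-10 family, not called with every rat, was called lower in 6. Over these fits the medians ran from 0.25 to 0.46 for miR-34/miR-449, 0.24 to 0.45 for miR-17-92, 0.14 to 0.32 for the X-linked cluster, -0.49 to -0.19 for let-7 and -0.36 to -0.07 for miR-200. For the trend, the X-linked cluster alone among miRNA lists was called (15 of 16 positive, median 0.38 per ppm, adjusted p = 0.00167, or 0.197 with an estimated correlation). That call stayed with each rat left out, with medians from 0.26 to 0.44, and miR-200 gained a trend call in 8 of the 23 fits, the miR-10 family and the muscle and stroma list in 5 each, and let-7 in 1. Of the tRNA lists, 7 were called between the ozone groups, among them tRNA-Asp-GTC (13 of 14 positive, median 0.28), tRNA-Gly-GCC (0 of 11 positive, median -0.41) and tRNA-Val-CAC (0 of 6 positive, median -0.44), each with an adjusted p of 0.753 with an estimated correlation. Quantile normalization ended the Gly-GCC call (adjusted p = 0.253), and without 0.8 ppm replicate 5 Asp-GTC was not called (median 0.14, adjusted p = 0.112). The 7 calls stayed in 10 to 23 of the 23 fits with 1 rat left out, where the medians ran from 0.13 to 0.40 for Asp-GTC, -0.56 to -0.30 for Gly-GCC and -0.58 to -0.32 for Val-CAC. For the trend 5 were called, all with an adjusted p of 0.571 or more with an estimated correlation, and they stayed called in 16 to 23 fits. The mitochondrial noncoding transcripts, not called with every rat (adjusted p = 0.131 between the ozone groups), were called higher at 0.8 than at 0.4 ppm in 4 of the 23 fits and for the trend in 1. Adjusted over the list alone, 1 of 3 tRX-Arg-NNN rows passed between the ozone groups (limma adjusted p = 0.0183) and 1 of 9 tRNA-Gln-CTG rows for the trend (0.0109), and no miRNA list had a member that passed. With library weights limma called 3 miRNAs and 32 tRNA rows for the trend.

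The spread between rats limits what these counts exclude. The 95% interval of the fold change at 0.8 ppm lay within 2-fold of air for 92 of the 100 most abundant miRNAs, 95 of the 100 most abundant tRNA rows, 88 of the 100 most abundant piRNA rows and 67 of the 100 most abundant Ensembl transcripts. Over all tested features it did so for 63.1%, 91.2%, 38.4% and 55.4%. At 0.4 ppm it did so for 87, 94, 39 and 59 of the 100 most abundant of each table, and for 57.7%, 88.6%, 35.2% and 49.8% of all tested features, and between the ozone groups for 85, 99, 63 and 68. Larger changes are not excluded for the rest.

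The mean log2 level of the miR-34/miR-449 family correlated with log2 miRNA reads over 23 libraries (Pearson r = 0.85, permutation p = 2e-05; Spearman rho = 0.83, permutation p = 2e-05; adjusted p = 1.1e-04 and 7.33e-05 over 11 lists). Without the 2 libraries farthest from the median depth r was 0.79, and within air, 0.4 ppm and 0.8 ppm it was 0.73, 0.92 and 0.84. The let-7 family ran the other way (r = -0.72, permutation p = 6e-05; rho = -0.82, permutation p = 1e-05, the smallest that the permutations can give; adjusted p = 2.2e-04 and 5.5e-05). Its r was -0.84 without the 2 farthest libraries, and -0.91, -0.66 and -0.70 within the groups.

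**Figure D3:**
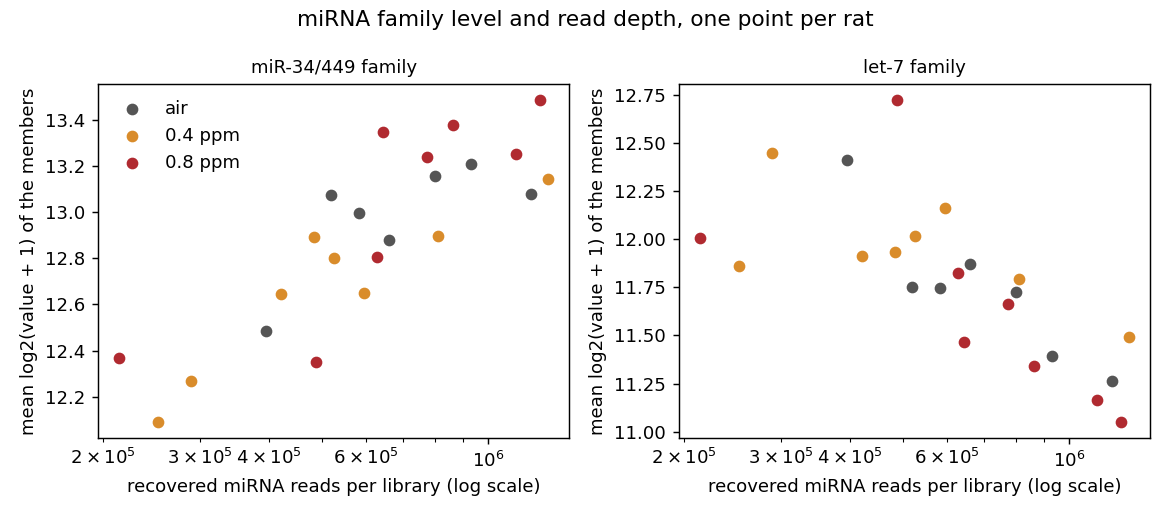
Mean log2(value + 1) of the miR-34/miR-449 and let-7 members (vertical axes) against recovered miRNA reads per library (horizontal axes, log scale); each point is a rat, coloured by group. The miR-34/miR-449 level rises with reads (r = 0.85) and the let-7 level falls (r = -0.72) in each group.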

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

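In 204 tests of a group's highest or lowest rat, 22 stood apart by a gap larger than Dixon's 95% value, where chance gives about 1 in 20. Chosen only after the results were seen were the tests of ozone as the source of the depth relation, of depth and of other cell types for the miR-200 list, of tRNA depth, of reads shared between tRNA genes, and of dose order.

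At 0.8 ppm, replicate 7 had 11.3% of its miRNA table in the muscle and stroma list (next highest 3.09%) and 4.75% in the leukocyte list (next 2.69%). Replicate 5 of that group, the library with the fewest miRNA reads, had 2.95% in the miR-200 list (next 1.37%), 15.6% of its Ensembl table in mitochondrial noncoding transcripts (next lowest 49.5%), 73.8% in nuclear protein-coding transcripts (next 41.0%), and 11.7% of its piRNA table in the 10 most abundant rows (next lowest 18.6%). Its log2 values were 14.2 for AY172581.24 and 10.0 for AY172581.9. In air, replicate 6 had 30.8% in the miR-34/miR-449 family (next lowest 42.9%), 4.81% in the leukocyte list (next 2.95%) and a log2 value of 16.9 for miR-34c-5p. At 0.4 ppm, replicate 6 had 16.3% of its piRNA table in the 10 most abundant rows, and log2 values of 13.8 for AY172581.24, 10.3 for AY172581.9 and 7.22 for miR-3590-5p. Replicate 5 there had a piRNA table total of 26946000 and a log2 value of 4.85 for tRNA-Trp-CCA-1-1, replicate 2 had 14.7 for Pcdhga7, and replicate 8 had 0.84 for piR-rno-227431. Air replicate 2 had 5.58 for miR-125b-5p, and Synpo2 had log2 values of 0.0244 in air replicate 7 and 0.0345 in 0.8 ppm replicate 6.

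Libraries with more miRNA reads had more miR-34/miR-449 and less let-7. Counting noise is argued against by its size: with every library thinned to 213839 reads, the mean counting SD of the miR-34/miR-449 score was 0.0727. The SD of that score between libraries was 0.385. Thinning itself left r at 0.85, and noise of this size could hardly have moved it. The family's own reads in the total are argued against as the whole source, since r was 0.74 with the reads of other miRNAs and 0.67 with tRNA reads (permutation p = 4.2e-04). Ozone is argued against, since r was 0.84 after group means were subtracted. For the share of other cells, the leukocyte, erythroid, and muscle and stroma lists had r of -0.08, 0.02 and -0.17 with log2 miRNA reads, and the miR-200 list -0.47. Within the groups the r of the leukocyte, erythroid, and muscle and stroma lists changed sign, so the share of other cells stays open. Sperm yield and RNA quality were not tested and stay open too. The labels give none of these per rat.

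The mean log2 level of the miR-200 list was 0.47 higher at 0.4 ppm than in air (exact permutation p = 0.0165), which did not pass over 11 lists (adjusted p = 0.0906). Lower depth in that group does not account for it, since the median log2 fold change was 0.48 with depth as a covariate against 0.53 without. Whether RNA from every other cell type rose alike cannot be told. The leukocyte list differed from the miR-200 change (exact permutation p = 0.0227, the smaller of 2 such tests). That test favours a difference, because the miR-200 list was taken up for its rise, the largest of the 11 lists. Leukocyte members also went both ways (3 of 8 higher). The difference from the 3 erythroid miRNAs had an exact permutation p of 0.428. The muscle and stroma score was 0.37 higher and did not pass either (exact permutation p = 0.0131, adjusted p = 0.0906), nor was the miR-200 change separated from it (difference 0.09, exact permutation p = 0.716). More RNA of epithelium, alone or with muscle, stroma or other cells, stays open as a candidate source. A dose order cannot be told apart from none, because the 0.8 ppm score lay below that at 0.4 ppm by less than the spread (exact permutation p = 0.347).

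Library differences linked to tRNA depth are argued against for the lower share of the 10 most abundant tRNA rows at 0.8 ppm, whose difference from air was -4.65 percentage points with the slope on log2 tRNA reads taken out (exact permutation p = 7.77e-04); thinning to 164342 reads (-4.47) could hardly have moved it, with a counting SE of 0.0618. The way shared reads are divided among genes of the same amino acid is argued against, because sums by amino acid do not depend on it. The 2 most abundant sums together held 67.4% ± 2.25 at 0.8 ppm (SD, n = 8) against 71.6% ± 1.23 in air (n = 7, exact permutation p = 0.00186). Neither was separated from air on its own (Gly -3.43 percentage points, exact permutation p = 0.314, and Leu -0.74, p = 0.78). These sums hold most of the same abundant rows, so they are not a separate measure. They cannot decide on reads counted at more than 1 gene, which summing does not remove. The trend with ppm over 23 libraries had r = -0.56 (permutation p = 0.0065) and rho = -0.58 (permutation p = 0.0047). It rests largely on the 0.8 ppm difference from air that prompted it, since 0.8 ppm was not separated from 0.4 ppm (-3.26 percentage points, exact permutation p = 0.0746, adjusted p = 0.382). An effect of ozone on reads assigned to tRNA genes may be followed up as a hypothesis, found and tested on the same data. Reads counted at more than 1 gene, reads shared across amino acids, or a sequencing pool or RNA quality that differed between groups, were not tested and stay open.

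The splits of the rats, 100 for each result with the real one included, show whether chance can be excluded. For counts at an unadjusted p under 0.05 it could not. At 0.4 ppm against air, 38 splits gave as many miRNAs (real 22, highest other 54), 32 as many tRNA rows (16, 83), 36 as many piRNA rows (1417, 3911) and 59 as many Ensembl transcripts (19, 87). At 0.8 ppm against air the numbers were 62 (9, 71), 49 (5, 69), 68 (723, 3893) and 75 (12, 104). Between the ozone groups they were 69 (15, 65), 71 (6, 62), 89 (804, 6339) and 87 (14, 156), and for the trend 82 (9, 95), 80 (5, 86), 92 (715, 5088) and 86 (12, 121). Splits that call several times the real count point to a structure of the samples other than their groups or to features that vary together, which no test told apart.

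For lists called with the preset correlation chance could not be excluded either. For miRNA lists 5 splits gave as many at 0.4 ppm against air (real 5, highest other 5), 27 at 0.8 ppm (3, 6), 12 between the ozone groups (5, 7) and 67 for the trend (1, 7). For tRNA lists 16 did at 0.4 ppm (10, 12), 65 at 0.8 ppm (6, 13), 57 between the ozone groups (7, 12) and 82 for the trend (5, 13), and the median of the other splits was 7 called tRNA lists. For Ensembl lists the real count was 0, so that every split, 100 of 100, gave as many in each contrast (highest other 2), and the splits cannot bear on chance there. With library weights 6 splits gave as many miRNAs at 0.4 ppm (2, 15), 5 at 0.8 ppm (3, 20) and 5 for the trend (3, 43), and 9 gave as many tRNA rows at 0.8 ppm (22, 78). For the weighted tRNA trend 4 did (32, 77), the only share under 0.05 among the 29 results with a real count above 0, where chance gives about 1 in 20.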

How the results depend on the processing

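Chosen after the data were seen were depth as a covariate, merging identical piRNA rows, and leaving out the 3 libraries with the fewest miRNA reads. So was leaving out each rat for the library measures and list tests. Depth as a covariate was log2 miRNA reads in every table. Limma counts of 0 stayed at 0 under the other pseudocounts, filters and scalings, quantile normalization, the exact Wilcoxon test (not run for the trend), edgeR and DESeq2 on miRNA reads, fits to the compared groups alone, the residual component, depth as a covariate, summed tRNA rows and merged piRNA rows. Every tRNA, piRNA and Ensembl row was above 0 in all 23 libraries, so the filters could change the miRNA counts alone. With 7 or 8 rats per group, the exact Wilcoxon test could not call a lone feature against air, even one separating the groups fully. Its count of 0 does not bear on such a feature. That test could call a piRNA only if many rows separated the groups fully or nearly so. Library weights, which count libraries with larger residuals less, gave 2 miRNAs at 0.4 ppm, 3 at 0.8 ppm and 3 for the trend, and 22 tRNA rows at 0.8 ppm and 32 for the trend; the cause was not tested. Without the 3 libraries with the fewest miRNA reads, 1 piRNA was called at 0.4 ppm against air and 1 between the ozone groups, piR-rno-346434 both times. With each rat left out in turn, piRNA counts ranged from 0 to 2 at 0.4 ppm (1 without air replicate 2, 2 without 0.4 ppm replicate 5) and from 0 to 1 between the ozone groups (1 without 0.4 ppm replicate 5). Ensembl counts between the ozone groups ranged from 0 to 1 (1 without 0.4 ppm replicate 3). Family shares that passed ranged from 0 to 3 (1 without air replicate 1, 3 without air replicate 6), and library measures from 1 to 2 (2 without air replicate 6, the miRNA measure at 0.4 ppm being the other). Over the 4 contrasts the preset correlation called 14 miRNA lists and 28 tRNA lists, an estimated correlation 0 and 0, and quantile normalization 9 and 16; depth as a covariate called 7 and 22, and the residual component 13 and 29. No Ensembl list was called under any of these. With each rat left out the preset correlation called 11 to 17 miRNA lists, 16 to 30 tRNA lists (16 without air replicate 1) and 0 to 3 Ensembl lists (1 without 0.4 ppm replicate 7 or 0.8 ppm replicate 3 or 7, 3 without 0.8 ppm replicate 5). With the 50 most abundant rows 0 library measures passed, and the tRNA difference at 0.8 ppm was -1.6 percentage points. That difference with 10 rows ranged from -4.90 to -4.02 with each rat left out and passed each time (adjusted p from 0.0105 to 0.036). No feature named for its smallest unadjusted p changed direction. The 2 fractional tables give no depth, and the depth behind their values is unknown.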

Other observations

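The correlations with depth here were chosen after the data were seen; library weights and leaving out each rat from the feature tests were planned. The miR-17-92 and related clusters, which growing cells express, moved with the germ-cell miRNAs from rat to rat. Their mean log2 level correlated with log2 miRNA reads (Pearson r = 0.86, permutation p = 1e-05; Spearman rho = 0.90, permutation p = 1e-05, the smallest the permutations can give; adjusted p = 1.1e-04 and 5.5e-05 over 11 lists). r was 0.87 without the 2 libraries farthest from the median depth, and 0.77, 0.91 and 0.84 within air, 0.4 ppm and 0.8 ppm. The X-linked miR-506 cluster had r = 0.54 (permutation p = 0.00822, adjusted p = 0.0203) and rho = 0.56 (permutation p = 0.00683, adjusted p = 0.0188), with 0.95, 0.22 and 0.81 within the groups and 0.61 without the 2 farthest libraries.

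Other lists followed depth less closely. The miRNAs tied to paternal stress had r = 0.52 (permutation p = 0.00921, adjusted p = 0.0203) and rho = 0.43 (permutation p = 0.0395, adjusted p = 0.0724), with r = 0.49 without the 2 farthest libraries and 0.53, -0.26 and 0.96 within the groups. The miR-10/miR-99/miR-100/miR-125 family had r = -0.47 (permutation p = 0.0237, adjusted p = 0.0372) and rho = -0.46 (permutation p = 0.0293, adjusted p = 0.0645), with r = -0.51 without the 2 farthest and -0.10, -0.74 and -0.31 within the groups. The miR-200 family had r = -0.47 (permutation p = 0.0226, adjusted p = 0.0372) and rho = -0.31 (permutation p = 0.158, adjusted p = 0.248). Its r was -0.14 without the 2 farthest libraries, so it rests on them, and -0.43, -0.15 and -0.71 within the groups. The leukocyte, erythroid, muscle and stroma, and redox and hypoxia lists had r of -0.08, 0.02, -0.17 and 0.21 (permutation p = 0.719, 0.942, 0.44 and 0.338, adjusted p = 0.791, 0.942, 0.538 and 0.465). Their rho was -0.01, -0.01, -0.16 and 0.10 (permutation p = 0.976, 0.958, 0.464 and 0.66). Without the 2 farthest libraries r was 0.45, 0.25, -0.15 and 0.53. The leukocyte and erythroid lists had r of 0.07 and -0.42 in air, 0.46 and 0.47 at 0.4 ppm, and -0.77 and -0.71 at 0.8 ppm. The muscle and stroma list had 0.83, -0.44 and -0.33 within the groups, and the redox and hypoxia list 0.58, 0.39 and -0.36.

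The 5 features with the smallest p among those called under an alternative alone were 3 piRNAs, 1 tRNA row and 1 Ensembl transcript. Without air replicate 2, piR-rno-227431 had a log2 fold change of -2.36 at 0.4 ppm against air (limma adjusted p = 4.7e-04). Without 0.4 ppm replicate 5, piR-rno-346434 had -2.86 at 0.8 against 0.4 ppm (limma adjusted p = 0.00546) and 2.87 at 0.4 ppm against air (0.0089), and piR-rno-285206 had -3.43 at 0.4 ppm against air (0.0333). With library weights tRNA-Gln-CTG-2-2 had a slope of 1.60 per ppm (limma adjusted p = 7.06e-04) and a log2 fold change of 1.26 at 0.8 ppm (0.0014). That row is low, averaging 10.9 ± 4.95 in air (SD, n = 7). Without 0.4 ppm replicate 3, the transcript ENSRNOT00000100586, which has no RefSeq match, had 1.43 at 0.8 against 0.4 ppm (limma adjusted p = 0.00945).

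The miRNAs called with library weights are named as chosen after their values were seen. At 0.8 ppm, miR-471-5p had a log2 fold change of 1.21, miR-17-2-3p of 1.07 (limma adjusted p = 0.0204 for both) and miR-741-3p of 0.79 (0.0241), and the trend called the same 3. At 0.4 ppm, miR-3590-5p had -1.02 and miR-429 0.88 (limma adjusted p = 0.0468 for both).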
